A study of Rattus norvegicus with 24 samples.

How the data were processed

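The deposited table holds 1 intensity per probe set for each of 24 Affymetrix Rat RAE 230 2.0 arrays, and per the submitters' processing notes these are MAS5 signals. The MAS5 version is not stated. Per the series description, RNA came from 6 brain regions of 28 male rats, 8 SHR, 8 WKY, 8 SD and 4 SD-PCB, at postnatal day 55 to 65, and per the labels RNA was purified with RNeasy columns (Qiagen) and labelled with the Ovation kit (Nugen). The values are linear and above 0, and the 2% trimmed mean of each array over all probe sets is close to 500 (median over arrays 500.2), which is the scaling of the deposited values. No further normalization between arrays was seen, and detection calls are not given, so the background of a probe set is unknown. Whether RNA of several rats was pooled on an array is not stated. Array scan dates and batches are not given.

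Of the 31099 probe sets, 57 control probe sets were set aside and 31042 kept. The platform table gave 1 gene symbol to 20826 of them, several symbols to 436 and none to 9780, and chromosomes were taken from the GRCr8 annotation. Signals were transformed as log2(signal + 1), and the 15521 probe sets with a mean at or above the median, a mean signal of about 117, were tested; they represent 9009 genes. A gene was represented by its brightest probe set among those with 1 symbol.

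Differences between strain groups were fitted with limma 3.58.1 in R 4.3.3, with strain group and region as terms (15 residual degrees of freedom), empirical Bayes moderation with a trend on mean signal, two-sided tests, and Benjamini-Hochberg adjustment over probe sets with a threshold of 0.05. There is 1 array per strain group and region, so the regions serve as the repeated values. The 6 regions of a strain group come from the same set of rats, so these p-values measure agreement between regions, not between animals, and are too small for a statement on strains or exposure. The difference of the models was tested as a contrast of contrasts, and the striatum term as the strain group difference in both striatal regions minus that in the other 4 regions (12 residual degrees of freedom). Regions were described by each region minus the mean of the other 5, with adjusted p under 0.05 and a log2 difference of at least 1. Within a region only values are given; the median of a list there was set beside 10000 random lists matched on mean signal.

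There were 38 gene lists with 589 genes, of which 365 were tested. They covered transmitter systems, epigenetic regulators, known targets of biphenyls and of thyroid hormone, cell processes, and markers of cell types and regions, including meninges, vessels, choroid plexus and blood, which a dissected sample can also hold. The study's own set of 308 probe sets for 218 genes is not given here. The 34 lists with at least 4 genes tested were tested with camera at a preset correlation of 0.01, two-sided, on 1 probe set per gene. With an estimated correlation 0 lists passed in each of the 4 comparisons, where 3, 4, 4 and 5 had an unadjusted p under 0.05 for SHR minus WKY, SD-PCB minus SD, SHR minus SD and WKY minus SD. The fry test, which asks whether the genes of a list move on balance one way and compares them with no other genes, passed 14, 14, 14 and 12 lists. Where the count of members past the threshold differs when adjusted over the list alone, it is given beside the count over all probe sets; elsewhere the 2 counts are equal.

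The tests, the filter, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison of strain groups, the 8 largest rises and 8 largest falls among genes past the threshold with 1 sign in all 6 regions. It names up to 4 members past the threshold for each list, or for a list described with none the 2 with the smallest p, as values. It names label checks (Th, Slc6a3, Drd1, Drd2, Pcp2, Gabra6, Neurod6, Prox1, Xist) and the 5 highest genes of each region. Within a region it names the 2 highest and 2 lowest among the brightest 25% of genes, as values. It also names the 5 smallest p-values for the difference of the models and the striatum terms. Zbtb47 and genes named in the closing section for tissue composition fall outside it and were chosen after their values were seen.

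The alternatives set at that point were quantile normalization, centring each array on its median, a pseudocount of 16, no filter, the upper 25% by mean signal, no trend, array weights and 1 probe set per gene. Others were leaving out the arrays of each region in turn, fits on the arrays of 2 strain groups, other thresholds (adjusted p 0.1, log2 0.5), an exact sign-flip permutation over regions for named genes, and other list tests. Cyclic loess normalization, 2 array measures as covariates, leaving out a pair of arrays, and quantile normalization with the upper 25% were added after the data were seen. The chain was tested on simulated data: with 67 probe sets changed 1.5-fold, 30 were found, with 67 changed 2-fold 56 and with 66 changed 4-fold 66. Of 160 calls 8 were false, and 0 calls were made by limma in an unchanged comparison.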

Results

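The series compared a genetic and an environmental rat model of attention deficit hyperactivity disorder by messenger RNA in the brain. The spontaneously hypertensive rat (SHR), an inbred strain used as the genetic model, stands beside its parent strain, the Wistar-Kyoto rat (WKY). Sprague-Dawley rats exposed to polychlorinated biphenyls (SD-PCB), the environmental model, stand beside unexposed Sprague-Dawley rats (SD). The 24 arrays cover 6 regions: dorsal striatum, ventral striatum, prefrontal cortex, hippocampus, substantia nigra with the ventral tegmental area (VTA), and the vermis of the cerebellum. Each of the 4 strain groups gave 1 array per region, so no region has a replicate within a strain group. The 28 male rats (8 SHR, 8 WKY, 8 SD and 4 SD-PCB) were taken at postnatal day 55 to 65; whether an array held RNA of several rats is not stated. Log2 differences below are means over the 6 regions ± the standard error of the limma fit (n = 6 within-region differences), and signals are linear MAS5 units ± SD (n = 6 arrays).

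Median signal was 163 ± 19.7 on the SD arrays, 98.3 ± 13.8 on the SD-PCB arrays, 153 ± 17.0 on the SHR arrays and 121 ± 16.2 on the WKY arrays (SD over 6 arrays each). The share of probe sets under a signal of 50 was 21.4%, 37.4%, 23.5% and 31.2% in the same order. The log2 ratio of the 3' to the 5' Gapdh probe set, a measure of how complete the labelled RNA was, averaged 2.04, 1.196, 1.53 and 1.91. The same ratio came in other orders for beta-actin (3.87, 3.59, 3.78 and 4.30) and hexokinase (1.60, 2.69, 2.30 and 3.06), so these ratios give no common order of RNA completeness. The 18 bacterial and phage probe sets that report added hybridisation controls differed between strain groups by a median log2 of 0.56 for SHR minus WKY, -0.77 for SD-PCB minus SD, -0.76 for SHR minus SD and -1.36 for WKY minus SD. Median signal, the share of dim probe sets, the Gapdh ratio and the added controls therefore moved with the strain groups, and each gene group below moved on the same arrays. The number of arrays limits the precision of every value.

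**Figure D1:**
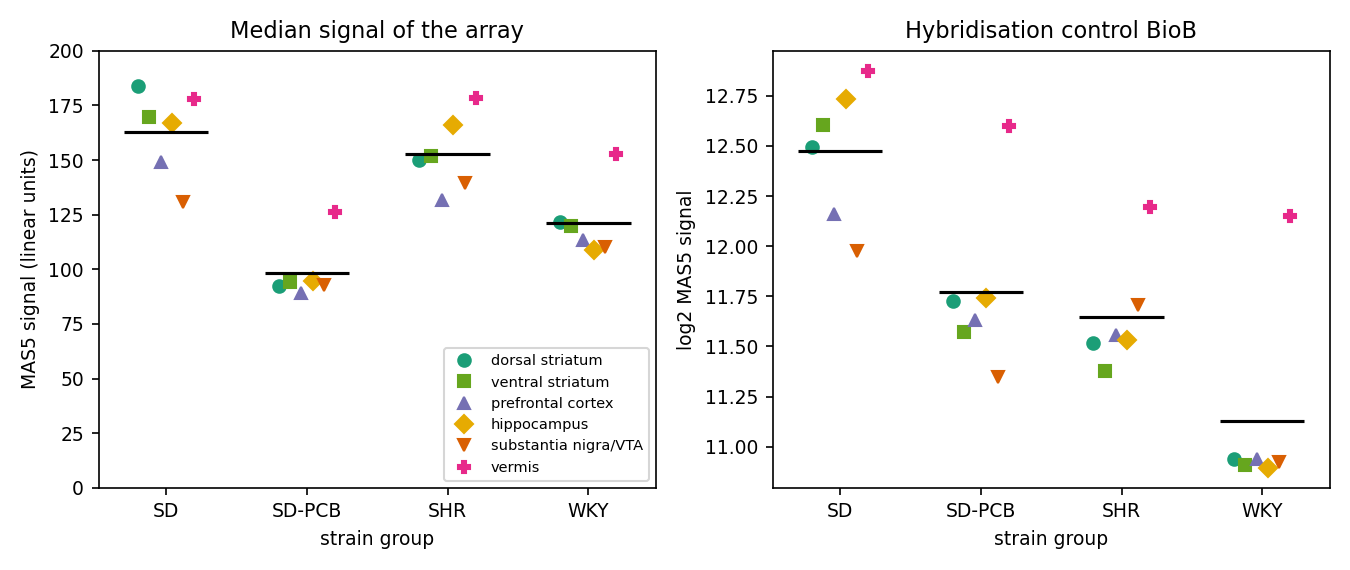
Left: median MAS5 signal of each of the 24 arrays (linear units). Right: log2 signal of the hybridisation control BioB. Points are arrays, shaped and coloured by region, and black lines are means of the 6 arrays of a strain group. The mean of the median signals was 163 in SD and 98.3 in SD-PCB, and the vermis array of the SD-PCB group stood at 126.

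Each of the 6 regions was set apart by a set of transcripts, a part of them known from its cell types. The dorsal striatum was marked by the adenosine receptor Adora2a (log2 5.45 ± 0.50 against the mean of the other 5 regions), the signalling protein Rgs9 (4.36 ± 0.31), the G protein subunit Gng7 (4.22 ± 0.35), Syndig1l (4.14 ± 0.39) and the dopamine receptor Drd2 (3.96 ± 0.37). The ventral striatum had Adora2a (4.39 ± 0.50), Ankrd63 (3.59 ± 0.36), Rgs9 (3.44 ± 0.31), the dopamine receptor Drd1 (3.21 ± 0.24) and Gng7 (3.12 ± 0.35). Vip and Cck, neuropeptides of cortical interneurons, led in the prefrontal cortex (3.47 ± 0.66 and 2.91 ± 0.46), followed by Tnnc2 (2.71 ± 0.25), Catsperz (2.69 ± 0.18) and Mlip (2.64 ± 0.21). The hippocampus was marked by Fibcd1 (3.43 ± 0.48), Pkp2 (3.40 ± 0.28), Nts (3.17 ± 0.44) and Neurod6 (3.05 ± 0.32). Ttr, known from the choroid plexus (3.90 ± 0.80), was highest there only in SD (SD-PCB 3876 against 20978 in vermis). In substantia nigra/VTA the vesicular glutamate transporter Slc17a6 (3.96 ± 0.33), the calcitonin receptor Calcr (3.48 ± 0.43), Gpx3 (3.47 ± 0.32), the receptor tyrosine kinase Ret (3.26 ± 0.24) and Fgf1 (3.22 ± 0.35) stood out. The vermis had the granule cell receptor subunit Gabra6 (8.80 ± 0.78), the Purkinje cell transcript Pcp2 (7.70 ± 0.55), Ppp1r17 (6.77 ± 0.60), Car8 (5.51 ± 0.26) and Atp2a3 (5.41 ± 0.29).

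All 10 striatal medium spiny neuron markers tested were higher in both striatal regions (median log2 3.30 and 2.80), and 10 of 12 cerebellar markers in the vermis (4.12). Higher in their own region were also 4 of 6 midbrain dopamine neuron markers in substantia nigra/VTA (2.17), 6 of 9 hippocampal markers in the hippocampus (1.76) and 5 of 11 cortical pyramidal neuron markers in the prefrontal cortex (0.92). Tyrosine hydroxylase (Th), the rate-limiting enzyme of dopamine synthesis, gave signals from 217 to 3742 in substantia nigra/VTA and at most 249 in the other regions. The dopamine transporter Slc6a3 gave 955 to 8411 there and at most 122 elsewhere. Prox1, a marker of dentate granule cells, was highest in the hippocampus (log2 1.76 ± 0.11), and Xist, the transcript of the inactive X chromosome, stayed at or below 176 on these arrays from male rats. Probe sets with limma adjusted p under 0.05 and a log2 difference of at least 1 numbered 801 in the dorsal striatum (479 higher, 322 lower) and 316 in the ventral striatum (249 and 67). There were 732 in the prefrontal cortex (440 and 292), 439 in the hippocampus (301 and 138), 1155 in substantia nigra/VTA (433 and 722) and 2378 in the vermis (978 and 1400). In all, 3463 probe sets passed in at least 1 region. Each region rests on 4 arrays from 4 separate sets of rats.

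The comparison of SHR with WKY asks what sets the genetic model apart from its control strain. The largest rise was Ephx2, soluble epoxide hydrolase, which inactivates epoxides of fatty acids: its signal was 537 ± 123 in SHR and 53.3 ± 15.3 in WKY, a log2 difference of 3.33 ± 0.21 (adjusted p = 4.66e-10), higher in 6 of 6 regions. Its gene lies on chromosome 15 of the GRCr8 annotation. The largest fall was Nt5dc1, a member of the 5'-nucleotidase family on chromosome 20, with -2.68 ± 0.16 (adjusted p = 3.53e-10), higher in 0 of 6 regions. Meningeal and vessel markers and the globin transcript Hbb were higher in SHR, and 6 of 19 calcium handling genes were lower. With an estimated correlation between genes none of the 3 lists passed in camera (meningeal adjusted p = 0.476, vessel 0.476, calcium 0.135).

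Next to Ephx2, the rises held the peroxisomal membrane protein Pxmp4 (2.84 ± 0.26), the uncharacterised gene RGD1309362 (2.73 ± 0.38), the kinesin Kif13a (2.40 ± 0.16) and Larp6, which binds collagen messenger RNA (2.28 ± 0.28). They also held the lysosomal protein Creg1 (2.02 ± 0.17), the dicarboxylate transporter Slc13a3 (2.01 ± 0.26) and the secreted glial protein Chi3l1 (2.00 ± 0.15). Among the falls were the phosphodiesterase Prune1 (-2.60 ± 0.18), the translation regulator Cpeb3 (-2.37 ± 0.21), the chromatin protein Hmgb1 (-2.13 ± 0.37) and Atxn7, a subunit of the SAGA transcription complex (-2.11 ± 0.30). The RNA-binding proteins Elavl1 (-2.08 ± 0.17) and Ro60 (-2.03 ± 0.46) and Ccdc71l (-1.87 ± 0.27) fell as well. All 16 had the same sign in 6 of 6 regions, which the rule for naming genes required. For Atxn7 another probe set rose by 0.60 ± 0.16 (adjusted p = 0.00861). For Elavl1 a second probe set gave -0.91 ± 0.26 (adjusted p = 0.0115) and another 0.78 ± 0.48 (adjusted p = 0.222).

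Of the meningeal and fibroblast markers, 9 of 10 rose and 0 fell (median log2 1.31, camera adjusted p = 3.56e-04, adjusted p = 0.476 with an estimated correlation). They included the prostaglandin synthase Ptgds (1.52 ± 0.21), the collagens Col1a1 (1.38 ± 0.23) and Col1a2 (1.43 ± 0.29), and Aldh1a2, which makes retinoic acid (1.29 ± 0.26). Of the endothelial and pericyte markers, 7 of 8 rose and 0 fell (median 1.03, adjusted p = 8.60e-04, adjusted p = 0.476 with an estimated correlation), among them the organic anion carrier Slco1a4 (1.27 ± 0.17), Vtn (1.45 ± 0.20), the tight junction protein Cldn5 (1.07 ± 0.18) and the efflux pump Abcb1a (1.29 ± 0.22). Hbb, beta globin and the blood cell marker that could be tested, rose by 1.71 ± 0.12 (adjusted p = 1.84e-09). Of the calcium release and handling genes, 0 of 19 rose and 6 fell (median -0.17, adjusted p = 0.0200, adjusted p = 0.135 with an estimated correlation): the sodium-calcium exchanger Slc8a1 (-0.67 ± 0.13), calmodulin Calm2 (-0.49 ± 0.12), the ryanodine receptor Ryr2 (-0.90 ± 0.23) and the channel Cacna1c (-0.61 ± 0.20) were among them. The calcium median was -0.083 with cyclic loess normalization, and as deposited -0.016 in the hippocampus. On the same arrays 25 of 45 control probe sets for non-rat sequences were higher in SHR, and 0 were lower. The call of Cacna1c (0.0949 without the dorsal striatum) ended when 1 region was left out (highest adjusted p).

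The other lists were not shifted as a whole, and some of their members passed, as did 3034 of all 9009 genes tested. For dopamine receptors and signalling, 2 of 13 higher and 1 lower were found: Caly, a partner of the D1 receptor (0.75 ± 0.13), and Ppp1r1b, known as DARPP-32 (0.58 ± 0.14), rose, while the phosphodiesterase Pde10a fell (-0.57 ± 0.15). In the list for dopamine synthesis and transport, 0 of 6 higher and 1 lower (0 and 0 adjusted over the list alone), the gene lower being Qdpr, which recycles tetrahydrobiopterin (-0.46 ± 0.17). Th and Slc6a3, bright only in substantia nigra/VTA, lay under the filter on mean signal over all arrays. Neither was tested in any comparison, so these counts do not speak to them. Glutamate receptors and transporters had 2 of 20 higher and 3 lower, with Grin1 at 0.62 ± 0.14, Gria3 at -0.63 ± 0.11 and the astrocytic transporter Slc1a2 at -0.51 ± 0.15. In the GABA system, 3 of 13 higher and 3 lower (3 and 4 adjusted over the list alone): the vesicular transporter Slc32a1 (0.89 ± 0.22) and the receptor Gabbr1 (0.41 ± 0.10) rose, and Gabra2 fell (-0.60 ± 0.19). Synaptic vesicle release had 2 of 12 higher and 2 lower (3 and 2 adjusted over the list alone), Syn1 rising (0.53 ± 0.14) and Vamp2 falling (-0.75 ± 0.17). Of the neurotrophin genes, 1 of 8 higher and 0 lower, the gene higher being the BDNF receptor Ntrk2 (0.73 ± 0.17). The medium spiny neuron markers had 1 of 10 higher and 2 lower, including the tachykinin precursor Tac1 (-0.67 ± 0.21). Midbrain dopamine neuron markers had 0 of 6 higher and 0 lower and cerebellar markers 2 of 12 higher and 0 lower (1 and 0 adjusted over the list alone). The hippocampal and cortical pyramidal lists had 1 of 9 higher and 0 lower (0 and 0 adjusted over the list alone) and 0 of 11 higher and 2 lower (0 and 0 adjusted over the list alone). In the midbrain list the vesicular monoamine transporter Slc18a2 had -0.41 ± 0.17 (adjusted p = 0.0685) and Ddc 0.51 ± 0.31 (adjusted p = 0.222), neither past the threshold. The calls of Qdpr (0.185 without substantia nigra/VTA), Slc1a2 (0.0591 without substantia nigra/VTA), Gabra2 (0.0861 without the ventral striatum) and Tac1 (0.0903 without the ventral striatum) ended when 1 region was left out (highest adjusted p).

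Genes of epigenetic regulation, which the design names as an interest of the study, went both ways in SHR. Histone deacetylases had 1 of 10 higher and 1 lower, with Sirt2 at 0.93 ± 0.15 and Hdac2 at -0.67 ± 0.11. Histone acetyltransferases had 2 of 11 higher and 4 lower (2 and 5 adjusted over the list alone): Kat5 rose (0.80 ± 0.17), while Crebbp (-0.58 ± 0.11) and Ep300 (-0.73 ± 0.16) fell. For DNA methylation and methyl binding, 0 of 11 higher and 2 lower, these being the demethylating enzymes Tet2 (-0.86 ± 0.29) and Tet3 (-0.84 ± 0.21). Histone methylation had 5 of 19 higher and 1 lower, Ehmt2 (0.72 ± 0.18) and Ezh1 (0.56 ± 0.17) rising. Chromatin remodelling had 4 of 15 higher and 3 lower: the SWI/SNF subunits Smarcb1 (0.70 ± 0.13), Smarcd3 (0.76 ± 0.15) and Smarca4 (0.72 ± 0.17) rose and Arid1a fell (-1.25 ± 0.25). The calls of Tet2 (0.0911 without the ventral striatum) and Ezh1 (0.0714 without the hippocampus) ended when 1 region was left out (highest adjusted p).

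Metabolic and glial lists held members past the threshold but were not shifted as a whole. Oxidative phosphorylation had 9 of 20 higher and 2 lower (10 and 2 adjusted over the list alone), with Cox4i1 at 0.66 ± 0.11, Sdhb at 0.64 ± 0.13, Uqcrc1 at 0.57 ± 0.13 and Ndufs1 at -0.44 ± 0.10. Cytosolic ribosomal proteins had 6 of 12 higher and 0 lower, for example Rpl18 (0.63 ± 0.11). Microglia markers had 4 of 11 higher and 0 lower: the receptors Csf1r (1.17 ± 0.24) and Trem2 (1.16 ± 0.30), the adaptor Tyrobp (1.01 ± 0.26) and complement C1qb (0.88 ± 0.29). Astrocyte markers had 4 of 11 higher and 1 lower, with Aldh1l1 (1.49 ± 0.23) and Gfap (0.75 ± 0.17) rising, and oligodendrocyte markers 2 of 13 higher and 0 lower, with Mal (0.56 ± 0.18) and Mag (0.79 ± 0.27). Of the oxidative stress genes, 2 of 16 higher and 3 lower: catalase (Cat) fell by 1.63 on the log2 scale (SE 0.14, adjusted p = 3.07e-08), and Gstm1 rose (0.63 ± 0.092). The thyroid list had 3 of 10 higher and 1 lower, Slco1c1, a thyroxine carrier, rising (1.06 ± 0.19). Cholesterol synthesis had 2 of 12 higher and 1 lower, Fdps (0.78 ± 0.14) rising and Insig1 (-0.54 ± 0.091) falling. The circadian list had 2 of 15 higher and 2 lower, Dbp at 0.42 ± 0.14 and the nuclear receptor Rora at -1.85 ± 0.41. Immediate early genes had 0 of 10 higher and 1 lower, the phosphatase Dusp1 falling (-1.70 ± 0.17). Heat shock proteins had 1 of 8 higher and 0 lower (Hsp90ab1, 0.50 ± 0.088), and the dioxin receptor targets 1 of 4 higher and 0 lower (Cyp1b1, 1.14 ± 0.32). Steroid receptors and synthesis had 0 of 7 higher and 1 lower (Tsc22d3, -0.93 ± 0.31; -0.60 without the substantia nigra/VTA arrays, adjusted p = 0.129). The MHC list had 1 of 4 higher and 0 lower (Cd74, 1.69 ± 0.38), and the choroid plexus list 1 of 7 higher and 0 lower (Igf2, 1.58 ± 0.38). The calls of C1qb (0.117 without the prefrontal cortex), Mal (0.0873 without the ventral striatum), Mag (0.112 without the prefrontal cortex) and Dbp (0.0904 without the prefrontal cortex) ended when 1 region was left out (highest adjusted p).

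Over the array, limma put 4972 of 15521 probe sets (32%) past an adjusted p of 0.05 for SHR minus WKY, 2542 higher and 2430 lower, and 3701 of them had the same sign in all 6 regions. With quantile normalization 2166 of 4692 were higher. Of those called in the dimmest 25% of tested probe sets by mean signal 74.6% were higher, and in the brightest 25% it was 34.1%. By gene, 3034 of 9009 passed, 1861 higher and 1173 lower. These p-values are too small as a statement on the strains, because the 6 regions of a strain group came from the same rats. Without the ventral striatum arrays 3216 probe sets passed, and with the median signal of the array as a covariate 853.

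The comparison of SD-PCB with SD asks what exposure to polychlorinated biphenyls changed within a strain. Immediate early genes were lower in exposed rats, 7 of 10: Dusp1, which switches off MAP kinases, fell by 1.97 on the log2 scale (SE 0.17, adjusted p = 2.80e-08), and the clock genes Per1, Per2 and Per3 fell with it. Most astrocyte markers and heat shock proteins were lower and most vessel markers higher, the last not in substantia nigra/VTA (median -0.25). With an estimated correlation between genes none of these 4 lists passed in camera (immediate early adjusted p = 0.345, astrocyte 0.257, heat shock 0.257, vessel 0.432). Against the same SD arrays the astrocyte median was also low in unexposed WKY (-0.46) and SHR (-0.48), beside -0.46 in SD-PCB. The astrocyte fall was therefore not particular to exposed rats. The vessel median went the other way in WKY (-0.41). The largest rises were Zfp593, a zinc finger protein (2.11 ± 0.36), Nhsl2 (1.52 ± 0.39), the class I MHC gene RT1-N3 (1.47 ± 0.31) and Tmbim4, a Golgi protein that limits cell death (1.47 ± 0.18, signal 3867 ± 1050.2 against 1362 ± 135, adjusted p = 3.96e-06). The largest fall was Ikzf2, a transcription factor of the Ikaros family (-2.75 ± 0.31, signal 152 ± 225 against 641 ± 268, adjusted p = 1.38e-06).

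Further rises were the apelin receptor Aplnr (1.45 ± 0.35), Dkc1, the pseudouridine synthase dyskerin (1.41 ± 0.34), the semaphorin Sema3g (1.38 ± 0.28) and Srp72, of the signal recognition particle (1.38 ± 0.16). For Srp72 another probe set gave 0.37 ± 0.14 (adjusted p = 0.0489) and another 0.10 ± 0.11 (adjusted p = 0.540). Further falls were the carboxylesterase Ces1c (-2.48 ± 0.34), the bile acid and steroid reductase Akr1d1 (-2.31 ± 0.34), the mitochondrial asparaginyl-tRNA synthetase Nars2 (-2.30 ± 0.28), Harbi1 (-2.27 ± 0.37), the ubiquitin ligase Trim6 (-2.24 ± 0.31), the proliferation marker Mki67 (-2.14 ± 0.30) and Rasl12 (-2.13 ± 0.30). Mean signals of these falls in SD-PCB were dim, from 72.5 (Harbi1) to 204 (Mki67), against 287 (Akr1d1) to 601 (Ces1c) in SD. They were not separated from the lower signal of dim probe sets on the SD-PCB arrays. All 16 had the same sign in 6 of 6 regions, which the rule for naming genes required.

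Of the immediate early genes, 7 of 10 fell and 0 rose (median log2 -1.03, camera adjusted p = 0.00741, adjusted p = 0.345 with an estimated correlation). Besides Dusp1 these included Nr4a3 (-1.07 ± 0.21), Egr2 (-1.32 ± 0.28) and the synaptic gene Arc (-1.35 ± 0.41). Of the astrocyte markers, 9 of 11 fell and 0 rose (median -0.46, adjusted p = 3.55e-06, adjusted p = 0.257 with an estimated correlation). Among them were the gap junction protein Gja1 (-0.72 ± 0.088), the glutamate transporter Slc1a3 (-0.52 ± 0.088), glutamine synthetase Glul (-0.46 ± 0.082) and Fgfr3 (-0.38 ± 0.073). With quantile normalization the astrocyte median was -0.29. Of the heat shock proteins, 5 of 8 fell (median -0.41, adjusted p = 0.0158, adjusted p = 0.257 with an estimated correlation), such as Hsph1 (-0.53 ± 0.078), the endoplasmic reticulum chaperone Hspa5 (-0.76 ± 0.11), mitochondrial Hspd1 (-0.40 ± 0.079) and Hsp90ab1 (-0.42 ± 0.088). Of the cytosolic ribosomal proteins, 5 of 12 fell, and 7 when adjusted over the list alone (median -0.22, adjusted p = 0.00629, adjusted p = 0.532 with an estimated correlation), for example Rpl4 (-0.50 ± 0.13) and Rpl19 (-0.49 ± 0.12). In the vermis the ribosomal median was 0.34, and without these arrays it was -0.34 over the other regions. Unexposed WKY had a like ribosomal median, -0.22, against the same SD arrays. Of the endothelial and pericyte markers, 6 of 8 rose and 0 fell (median 0.71, adjusted p = 0.00629, adjusted p = 0.432 with an estimated correlation): Abcb1a (1.21 ± 0.22), Slco1a4 (0.87 ± 0.17), Cldn5 (0.83 ± 0.18) and the angiopoietin receptor Tek (0.60 ± 0.18). With no filter on dim probe sets the immediate early, heat shock and ribosomal lists each had an adjusted p of 0.0547. Control probe sets for non-rat sequences fell on the same arrays, 39 of 45. The calls of Arc (0.0717 without the prefrontal cortex) and Tek (0.0663 without the prefrontal cortex) ended when 1 region was left out (highest adjusted p).

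**Figure D2:**
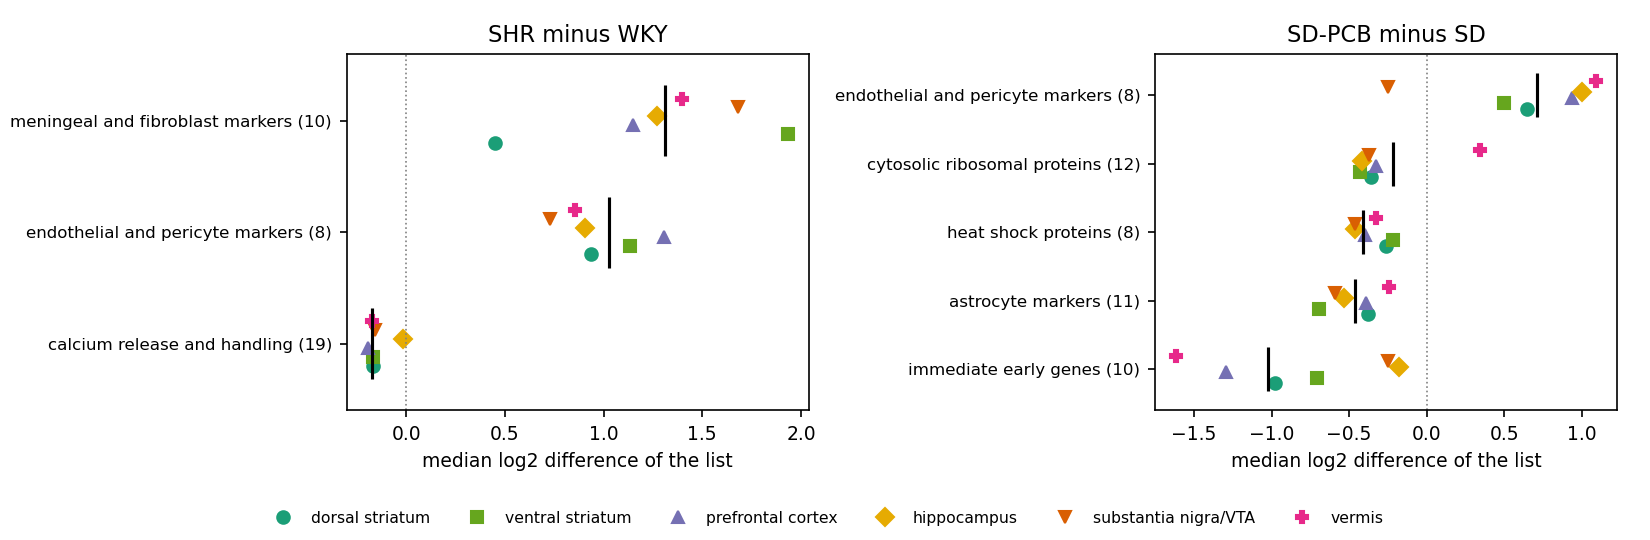
Median log2 difference of each shifted gene list (number of genes tested in brackets), for SHR minus WKY (left) and SD-PCB minus SD (right). Symbols are the 6 regions, 1 array against 1 array each, and black lines are medians of the fitted differences. Meningeal markers ran from 0.45 to 1.93 across regions in SHR, and immediate early genes from -1.62 to -0.18 in SD-PCB.

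The circadian list had 2 of 15 higher and 4 lower (3 and 4 adjusted over the list alone): the period genes Per1 (-1.69 ± 0.37), Per2 (-1.16 ± 0.16) and Per3 (-1.63 ± 0.26) fell and Tef rose (0.53 ± 0.093). Meningeal markers had 0 of 10 higher and 3 lower (0 and 4 adjusted over the list alone), with Col3a1 at -1.23 ± 0.24, Lum at -1.35 ± 0.32 and Aldh1a2 at -1.01 ± 0.26 (list adjusted p = 0.0749). Hbb rose by 1.06 ± 0.12. In the calcium list, which holds the ryanodine receptors on which non-dioxin-like biphenyls are known to act, 1 of 19 higher and 6 lower (2 and 8 adjusted over the list alone): the ryanodine receptor Ryr3 (-1.08 ± 0.19) and the kinase Camk2a (-1.25 ± 0.25) fell, and Calm2 rose (0.39 ± 0.12). Dioxin receptor targets had 0 of 4 higher and 1 lower, the gene lower being Cyp1b1 (-1.18 ± 0.32). Thyroid hormone action had 0 of 10 higher and 1 lower, myelin basic protein Mbp (-0.52 ± 0.11). Mbp is also counted among the oligodendrocyte markers, which had 1 of 13 higher and 5 lower, Cldn11 falling too (-0.53 ± 0.11). Of the oxidative stress genes, 1 of 16 higher and 1 lower (1 and 0 adjusted over the list alone), Gstp1 rising (0.59 ± 0.13) and the regulator Nfe2l2 falling (-0.61 ± 0.22; -0.37 without the prefrontal cortex arrays, adjusted p = 0.228, and -0.92 without the vermis). Cholesterol synthesis had 3 of 12 higher and 1 lower: Srebf2 (0.66 ± 0.095) and Sc5d (0.42 ± 0.088) rose and Lss fell (-0.63 ± 0.22). The calls of Calm2 (0.0981 without the dorsal striatum), Cyp1b1 (0.0572 without the dorsal striatum) and Lss (0.113 without the prefrontal cortex) ended when 1 region was left out (highest adjusted p).

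Transmitter lists were not shifted as a whole in SD-PCB minus SD. Some of their members passed, as did 2547 of all 9009 genes tested. Dopamine receptors and signalling had 2 of 13 higher and 0 lower, Rgs4 (0.66 ± 0.13) and Pde10a (0.48 ± 0.15), and the medium spiny neuron list had 2 of 10 higher and 0 lower, Tac1 rising (0.87 ± 0.21). Dopamine synthesis and transport had 0 of 6 higher and 1 lower (0 and 0 adjusted over the list alone), Pts, which makes tetrahydrobiopterin, falling (-0.67 ± 0.23). For glutamate receptors and transporters, 1 of 20 higher and 5 lower (1 and 6 adjusted over the list alone): Gria2 (-0.35 ± 0.074), Grm3 (-0.47 ± 0.11) and Grin2a (-0.79 ± 0.21) fell. The GABA system had 0 of 13 higher and 2 lower, such as Gabrb1 (-0.58 ± 0.12). Synaptic vesicle release had 2 of 12 higher and 3 lower: Vamp2 rose (0.56 ± 0.17) and Sv2b fell (-0.75 ± 0.11), while Snap25 fell (-0.30 ± 0.07) as deposited and turned to 0.31 with quantile normalization. The neurotrophin list had 0 of 8 higher and 1 lower, the receptor Ntrk3 falling (-1.49 ± 0.23). Microglia markers had 0 of 11 higher and 0 lower by limma (complement genes C1qc -0.67 ± 0.26, adjusted p = 0.0544, and C1qb -0.74 ± 0.29, adjusted p = 0.0548, turning to 0.0861 with quantile normalization). Midbrain dopamine and cerebellar markers had 0 of 6 higher and 0 lower and 0 of 12 higher and 4 lower, and hippocampal and cortical pyramidal markers 1 of 9 higher and 1 lower (0 and 1 adjusted over the list alone) and 0 of 11 higher and 2 lower. In the midbrain list Nr4a2 had -0.72 ± 0.37 and Calb1 0.16 ± 0.16, neither past the threshold, and Th and Slc6a3 lay under the filter and were not tested. The calls of Pde10a (0.108 without the hippocampus), Pts (0.101 without the prefrontal cortex) and Vamp2 (0.109 without substantia nigra/VTA) ended when 1 region was left out (highest adjusted p).

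Epigenetic regulators went both ways in SD-PCB minus SD too, and none of their lists was shifted as a whole. Histone deacetylases had 2 of 10 higher and 1 lower, Hdac2 (0.33 ± 0.11) and Hdac3 (0.39 ± 0.14) rising and Hdac8 (-0.36 ± 0.12) falling. With the median signal of the array as a covariate Hdac2 and Hdac3 turned to -0.25 and -0.52. Histone acetyltransferases had 1 of 11 higher and 2 lower: Kat7 rose (0.65 ± 0.10), and Ep300 (-0.77 ± 0.16) and the coactivator Ncoa3 (-1.29 ± 0.27) fell. DNA methylation and methyl binding had 1 of 11 higher and 1 lower (1 and 0 adjusted over the list alone), Mbd1 at 0.32 ± 0.087 and the methyltransferase Dnmt3a at -0.83 ± 0.31. Histone methylation had 1 of 19 higher and 5 lower (1 and 7 adjusted over the list alone), with the demethylase Kdm5a (-0.56 ± 0.12) and the methyltransferase Setdb1 (-0.68 ± 0.16) falling, and chromatin remodelling 2 of 15 higher and 3 lower, with Smarca5 (-0.51 ± 0.076) and Sin3a (-0.98 ± 0.26) falling. Oxidative phosphorylation had 0 of 20 higher and 2 lower (Atp5f1b -0.48 ± 0.11, Ndufs4 -0.68 ± 0.20). Steroid receptors and synthesis had 1 of 7 higher and 1 lower (2 and 1 adjusted over the list alone) (Hsd11b1 -0.46 ± 0.15; -0.28 without the substantia nigra/VTA arrays, adjusted p = 0.151). The MHC and interferon list had 0 of 4 higher and 1 lower (0 and 2 adjusted over the list alone) (Mx1 -1.01 ± 0.36), and the choroid plexus list 0 of 7 higher and 1 lower (Kcnj13 -1.48 ± 0.31). The calls of Hdac2 (0.0977 without the ventral striatum), Hdac3 (0.155 without the dorsal striatum), Hdac8 (0.115 without substantia nigra/VTA), Dnmt3a (0.106 without the dorsal striatum), Ndufs4 (0.0511 without substantia nigra/VTA) and Mx1 (0.132 without the hippocampus) ended when 1 region was left out (highest adjusted p).

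Over the array, 4894 of 15521 probe sets (31.5%) passed in limma for SD-PCB minus SD, 2274 higher and 2620 lower, and 3178 of them had the same sign in all 6 regions. By gene, 2547 of 9009 passed, 1331 higher and 1216 lower. With quantile normalization most were higher (2122 of 3767) and with no filter on dim probe sets most were lower (2480 of 11079 higher). Dim and bright probe sets went apart: of those called in the dimmest 25% by mean signal 10.03% were higher, and in the brightest 25% it was 60.8%. The p-values are again too small, as the regions came from the same rats, and exposure could not be separated from any difference in array processing between the SD-PCB and SD sets. With the Gapdh ratio of the array as a covariate 154 probe sets passed, and with its median signal 0 passed in limma, while 1639 of all tested had an unadjusted p under 0.05.

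The title of the series sets the genetic model against the environmental model, and the arrays of SHR minus WKY and of SD-PCB minus SD do not overlap. The models parted at Prune1 (a difference of -3.51 ± 0.25, from -2.60 in SHR minus WKY and 0.92 in SD-PCB minus SD), Nt5dc1 (-2.86 ± 0.23), Ephx2 (3.48 ± 0.30), the mitochondrial carrier of branched-chain amino acids Slc25a44 (-1.93 ± 0.18, from -0.56 and 1.37) and Htatsf1 (-1.48 ± 0.14, from -0.70 and 0.77). Meningeal markers (8 of 10 higher, 9 adjusted over the list alone, median 1.87), astrocyte markers (9 of 11, 0.65) and ribosomal proteins (8 of 12, 0.48) were higher in the genetic than in the environmental comparison. Their camera adjusted p-values were 7.34e-04, 8.33e-04 and 0.00697; they rose to adjusted p = 0.538, 0.538 and 0.859 with an estimated correlation. Without the filter on dim probe sets the ribosomal list had an adjusted p of 0.0599. With quantile normalization the astrocyte median was 0.33. The difference of the models passed for 6277 probe sets (3421 higher, 2856 lower), with p-values too small for the reason given above. Of 5059 with quantile normalization 2187 were higher, and of 13230 with no filter 10109. With the Gapdh ratio of the array as a covariate 2942 passed, and with its median signal 2.

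Genes were also counted by whether they moved the same way in both models. Of the 15521 probe sets, 177 were higher in both models where independent probe sets would give 372, 283 were lower in both (410 if independent), and 1183 went opposite ways (785 if independent). Array signal also went opposite ways. Among the dimmest probe sets called, 74.6% were higher for SHR minus WKY and 10.03% for SD-PCB minus SD. Among the brightest these shares were 34.1% and 60.8%. The added controls moved by a median log2 of 0.56 and -0.77. The count of opposite calls therefore cannot tell a difference between arrays from a difference between the models. Dusp1 was lower in both (-1.70 and -1.97), and Hbb (1.71 and 1.06), Abcb1a, Slco1a4 and Cldn5 were higher in both. Across the 9009 genes, which are not independent replicates, Pearson's r between the models was -0.25 and Spearman's rho -0.29. Chance is not excluded for the size of this r, as 16 of 100 splits gave one as large. By region r was -0.07 in the dorsal striatum, -0.29 in the ventral striatum, -0.03 in the prefrontal cortex, -0.19 in the hippocampus, -0.40 in substantia nigra/VTA and -0.01 in the vermis. It was -0.15 without the substantia nigra/VTA arrays, -0.12 with quantile normalization and 0.27 with the Gapdh ratio as a covariate. Against SD in place of WKY, SHR gave r = 0.15 with SD-PCB; these 2 differences share the SD arrays. Simulated unchanged groups gave 0.50 by construction, and sets of 3 regions that share no array a median of 0.0174. The covariance of these 2 differences was 0.032, and 0.020 in the simulated groups. WKY minus SD gave r = 0.48 with SD-PCB minus SD, again with the same SD arrays. In splits that share no array its median was 0.25 (0.17 to 0.33). Such splits still set SD rats on both sides, so a trait of the whole SD group stays in both differences.

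SHR and WKY were each also compared with SD, an outbred strain that stands outside the SHR and WKY pair. These 2 comparisons share the SD arrays, so a value that stands out in SD shows in both. Their r was 0.45, and simulated unchanged groups gave 0.50, a value that sharing a group gives by construction. This r alone therefore shows neither likeness nor its absence. Their covariance was 0.088, and 0.020 in the simulated groups. In 20 splits into sets of 3 regions that share no array, the median r was 0.26 (0.11 to 0.39). The SD arrays of both sets still came from the same SD rats. A trait of the whole SD group, array processing included, therefore stays in both differences. Some of the transcripts named were apart from SD in both. Fam111a, a restriction factor for viruses (-3.04 ± 0.39 in SHR, -4.24 ± 0.39 in WKY), Pop5, of ribonuclease P (-3.04 ± 0.12 and -2.95 ± 0.12), and the transcription factor Klf12 (-2.78 ± 0.34 and -2.22 ± 0.34) fell. In turn Dkc1 (2.23 ± 0.34 and 1.85 ± 0.34) and the presynaptic protein Prrt2 (2.00 ± 0.18 and 1.65 ± 0.18) rose. Dkc1 was also higher in SD-PCB than in SD (1.41), a comparison with the same SD arrays. Ephx2 (-3.04 ± 0.21), RGD1309362 (-2.64 ± 0.38), Kif13a (-2.50 ± 0.16) and Larp6 (-2.29 ± 0.28) fell in WKY against SD. In SHR against SD, Nt5dc1 (-2.81 ± 0.16), Elavl1 (-2.30 ± 0.17) and catalase (Cat, -2.04 ± 0.14) fell. Another probe set of Pop5 gave 0.10 ± 0.23 (adjusted p = 0.767) in SHR and -0.09 ± 0.23 (adjusted p = 0.819) in WKY.

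SHR minus SD further rose at Hps4, of lysosome-related organelles (2.52 ± 0.49), the lysosomal amino acid transporter Slc66a1 (2.38 ± 0.57), Pafah1b3 (2.27 ± 0.42), phosphomannomutase Pmm2 (2.02 ± 0.36), Sh3bgrl3 (2.02 ± 0.18) and Pdlim7 (2.01 ± 0.46; 1.20 without the vermis arrays, where it was 6.08). It fell at Clca1 (-2.51 ± 0.40), the protocadherin Pcdhb17 (-2.48 ± 0.34) and Coq10b (-2.47 ± 0.22). WKY minus SD further rose at Slc25a44 (2.10 ± 0.13; another probe set 0.08 ± 0.10, adjusted p = 0.622), LOC102553528 (1.96 ± 0.38), Amigo2 (1.91 ± 0.24), Zfp593 (1.80 ± 0.36), Eps15l1 (1.63 ± 0.35) and C10h5orf15 (1.57 ± 0.14; another probe set 0.27 ± 0.17, adjusted p = 0.298). It fell at Ces1c (-2.15 ± 0.34). Slc25a44 (1.37), Zfp593 (2.11) and Ces1c (-2.48) moved the same way in SD-PCB minus SD, a comparison with the same SD arrays. Hbb was 0.79 ± 0.12 in SHR and -0.93 ± 0.12 in WKY against SD.

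Against SD, 5 of 11 cortical pyramidal neuron markers fell in SHR and 0 rose (median -0.65, adjusted p = 0.00400, adjusted p = 0.130 with an estimated correlation): Rorb (-0.91 ± 0.18), Nptx1 (-0.92 ± 0.19), Mef2c (-0.45 ± 0.11) and Neurod6 (-1.15 ± 0.34). By region this median was -1.05 in the dorsal and -0.84 in the ventral striatum but -0.21 in the prefrontal cortex. Astrocyte markers had 2 of 11 higher and 6 lower (2 and 7 adjusted over the list alone) (median -0.48, adjusted p = 0.0113, adjusted p = 0.355 with an estimated correlation), Slc1a3 (-0.58 ± 0.088) and Glul (-0.52 ± 0.082) falling. Calcium handling genes had 1 of 19 higher and 8 lower (median -0.24, adjusted p = 0.0180, adjusted p = 0.126 with an estimated correlation): the calcium release channel Itpr1 (-0.64 ± 0.091), Fkbp1a (-0.47 ± 0.09), the calcium pump Atp2a2 (-0.38 ± 0.075) and Camk2b (-0.45 ± 0.09) fell. With quantile normalization the astrocyte and calcium medians of SHR minus SD shrank to -0.089 and -0.066 (adjusted p = 0.560 and 0.357), and with cyclic loess normalization to -0.196 and -0.15 (0.194 and 0.176). The call of Neurod6 (0.0693 without the ventral striatum) ended when 1 region was left out (highest adjusted p).

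In WKY against SD, 9 of 10 meningeal markers fell (median -1.21, adjusted p = 9.39e-08, adjusted p = 0.146 with an estimated correlation), among them Ptgds (-1.24 ± 0.21), Col3a1 (-1.36 ± 0.24), Col1a2 (-1.55 ± 0.29) and Lum (-1.58 ± 0.32). Astrocyte markers fell, 9 of 11 (median -0.46, adjusted p = 1.73e-07, adjusted p = 0.146 with an estimated correlation), with Slc1a3 at -0.71 ± 0.088 and Gja1 at -0.67 ± 0.088. With quantile normalization the astrocyte median was -0.18. Of the ribosomal proteins 4 of 12 fell, 7 adjusted over the list alone (median -0.22, adjusted p = 3.69e-04, adjusted p = 0.395 with an estimated correlation), such as Rpl3 (-0.48 ± 0.09) and Rpl5 (-0.44 ± 0.11). The ribosomal median was above 0 in the vermis (0.098) and -0.029 over all regions with quantile normalization. Of the vessel markers 3 of 8 fell, 4 over the list alone (median -0.41, adjusted p = 0.01001, adjusted p = 0.395 with an estimated correlation): Pecam1 (-1.35 ± 0.30), Vtn (-0.80 ± 0.20) and Slco1a4 (-0.67 ± 0.17). The cortical pyramidal list (2 of 11 lower, 3 over the list alone; median -0.43 and 0.07 in the prefrontal cortex; Mef2c -0.52 ± 0.11) had an adjusted p of 0.0224, and adjusted p = 0.296 with an estimated correlation. The oligodendrocyte list (4 of 13 lower; median -0.088; Mobp -0.84 ± 0.15, Mbp -0.48 ± 0.11) had 0.0373, and adjusted p = 0.557 with an estimated correlation. Both of these calls ended without the dorsal striatum arrays (adjusted p = 0.0640 for each) and with quantile normalization (0.0668 and 0.226). The oligodendrocyte median was -0.27 without the vermis arrays and -0.19 without substantia nigra/VTA, and this call also ended without the prefrontal cortex arrays (0.0891), and the ribosomal call with quantile normalization (0.276). With no filter on dim probe sets the adjusted p was 0.187 for the cortical pyramidal list, 0.236 for the oligodendrocyte list and 0.105 for the vessel list. The calls of Rpl5 (0.0527 without the ventral striatum) and Slco1a4 (0.0522 without the hippocampus) ended when 1 region was left out (highest adjusted p).

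By limma, 5187 probe sets passed for SHR minus SD (2930 higher, 2257 lower) and 2723 for WKY minus SD (1384 higher, 1339 lower), with p-values too small because regions shared rats. Of those called in the dimmest and the brightest 25%, 53.7% and 36.8% were higher for SHR minus SD and 23.05% and 47.0% for WKY minus SD. When each array was centred on its median, 2137 of 5215 were higher for SHR minus SD and 885 of 2696 for WKY minus SD. With cyclic loess normalization 1052 of 2225 were higher for WKY minus SD. For WKY minus SD the count fell to 1657 without the ventral striatum arrays, 1786 without the hippocampus and 1797 without the dorsal striatum, and to 74 with the median signal of the array as a covariate.

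The striatum, the main target of dopamine neurons, was tested for a strain group difference of its own against the other 4 regions. For SHR minus WKY, 0 probe sets passed in limma, and 344 had an unadjusted p under 0.05. The 5 genes with the smallest p were Trim16 (2.09 ± 0.46, adjusted p = 0.719), Tyw5 (-0.97 ± 0.25), Abhd17c (-1.08 ± 0.29), Cd83 (0.89 ± 0.24) and Spock1 (2.94 ± 0.82, adjusted p = 1), none past the threshold. For SD-PCB minus SD, 1 probe set passed, of the zinc finger gene Zbtb47 (4.08 ± 0.59, adjusted p = 0.0177), and 816 had an unadjusted p under 0.05. Zbtb47 was named after its value was seen, and its brighter probe set gave 0.38 ± 0.51 (adjusted p = 0.973). Values of the 5 genes with the smallest p were Dcakd 3.06 ± 0.51 (adjusted p = 0.0613), Lrrc4b 1.54 ± 0.27 (adjusted p = 0.0682), Rnf113a2 2.92 ± 0.60, Krt17 3.47 ± 0.72 and Stap2 2.76 ± 0.57 (adjusted p = 0.281). For SD-PCB minus SD the count was 12 without the dorsal striatum arrays, 8 without the ventral striatum and 2 without the vermis. It was 0 without the prefrontal cortex, the hippocampus or substantia nigra/VTA (1142, 941 and 704 at an unadjusted p under 0.05). For SHR minus WKY it was 1 without the dorsal striatum. The p-values treat regions of the same rats as independent and are too small. In simulated data this test found 158 of 200 probe sets changed 4-fold and made 15 false calls.

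Within a region, values rest on 1 array against 1 array and carry no test. For SHR minus WKY, Elavl1 was among the lowest of the brightest 25% of genes in the dorsal striatum (-2.09, with Purb -1.99), ventral striatum (-2.57, with Dusp1 -2.20) and prefrontal cortex (-2.26, with Dusp1 -1.93). The same held in substantia nigra/VTA (-2.26, with Cat -2.22) and vermis (-1.65, with Ranbp6 -1.71). Cat (-2.20) and Fubp3 (-1.97) were lowest in the hippocampus. The highest were tropomyosin Tpm1 (1.71) and dynamin Dnm1 (1.56) in the dorsal striatum, Ptgds (2.06) and Hbb (1.88) in the ventral striatum, and Ptgds (1.91) and the lipid carrier Apod (1.73) in the prefrontal cortex. They were Hbb (2.10) and the small heat shock protein Cryab (1.66) in the hippocampus, Tpm1 (1.94) and myosin Myl12a (1.51) in substantia nigra/VTA, and Hbb (2.01) and Jcad (1.76) in the vermis. The cerebellar marker list had its lowest value in the prefrontal cortex, a median of -1.27, below all 10000 random lists of like signal. That rank is over genes and says nothing of variation between samples. The WKY prefrontal array had a high signal of the cerebellar transcript Gabra6 (2297, against 28.8 in SHR).

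For SD-PCB minus SD, the dorsal striatum had parvalbumin Pvalb (2.33) and Fv1 (1.68) highest and Dusp6 (-1.58) and Nr4a3 (-1.41) lowest. The ventral striatum had Dipk2a (1.57) and the cannabinoid receptor Cnr1 (1.56) against Macf1 (-1.77) and Dusp1 (-1.71). The prefrontal cortex had Tmbim4 (2.26) and the chaperonin Cct6a (1.75) against Dusp1 (-2.70) and Dusp6 (-2.04). In the hippocampus Patj (1.64) and Tspyl2 (1.63) stood against Prrc2c (-1.56) and reelin Reln (-1.51). Substantia nigra/VTA had Plppr4 (2.63) and the synaptic vesicle protein Synpr (1.94) against Inf2 (-2.95) and the neurofilament Nefm (-2.27). The vermis had Srp72 (2.17) and the thyroid hormone binding protein Crym (2.09) against Nr4a3 (-2.79) and Dusp1 (-2.56). The midbrain dopamine neuron list had a median of -1.06 in substantia nigra/VTA and the oligodendrocyte list -1.03; Th there was 2223 in SD and 217 in SD-PCB, and Slc6a3 7789 and 955. In the same sample hypothalamic transcripts were higher, for example Pmch at 13017 against 2447.

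**Figure D3:**
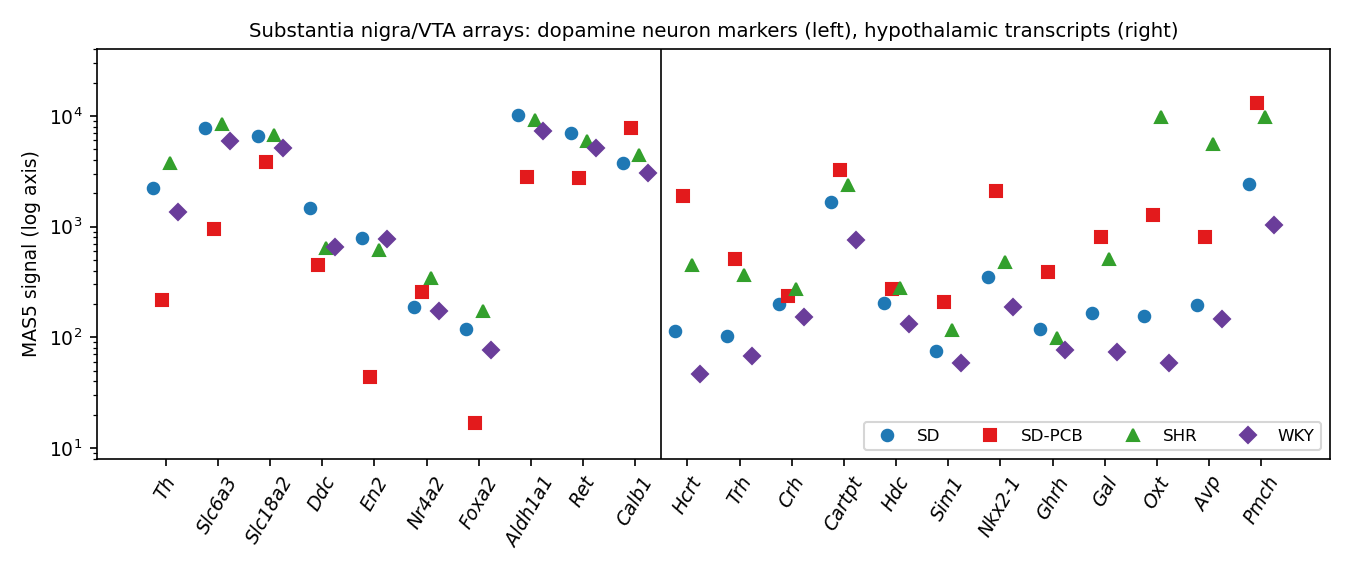
MAS5 signal (log axis) of midbrain dopamine neuron markers (left of the line) and hypothalamic transcripts (right of the line) on the 4 substantia nigra/VTA arrays, 1 symbol per strain group. Th was 217 on the SD-PCB array and 1367 to 3742 on the other arrays, and Oxt reached 9747 on the SHR array.

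Where a gene past the threshold had another tested probe set, its sign was the same for 628 of 868 such probe sets in SHR minus WKY (72.4%) and 543 of 879 in SD-PCB minus SD (61.8%). For genes with a log2 difference of 1 or more it was 42 of 68 and 35 of 40, and 7 and 1 of these other probe sets passed the threshold in the opposite direction. The median difference in SHR minus WKY was 1.299 by the brightest probe set of these genes and 0.22 in that direction by the others. Of the 100 largest differences past the threshold, 41 and 90 were probe sets without a single gene symbol. Noradrenaline, serotonin, acetylcholine and blood cell lists had 3, 3, 2 and 1 genes above the signal filter, under the minimum of 4 for a list test.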

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

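The tests of the array explanations for SD-PCB minus SD, of the sensitivity explanation for the dopamine transcripts, and of the vessel and meningeal markers were chosen only after the result was seen; the test of hypothalamic transcripts and the splits of the arrays were set beforehand.

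The 2 models differed from each other. By limma 6277 probe sets differed as deposited between SHR minus WKY and SD-PCB minus SD, led by Prune1 (-3.51), Nt5dc1 (-2.86), Ephx2 (3.48), Slc25a44 (-1.93) and Htatsf1 (-1.48), and the ribosomal (0.48), astrocyte (0.65) and meningeal (1.87) lists differed as a whole in camera. With an estimated correlation none of these 3 lists passed (adjusted p = 0.859, 0.538 and 0.538). With the Gapdh ratio of the array as a covariate 2942 probe sets differed, and with its median signal 2. Array processing stays open here, as the added controls went opposite ways in the 2 comparisons (median log2 0.56 and -0.77). Chance can be excluded for the number of probe sets, as 1 of 100 splits, the real one, gave as many (highest other 3267). Only the real split was as large, too, for SHR minus WKY (4972, 1 of 32 splits, highest other 2678) and SD-PCB minus SD (4894, 1 of 32, highest other 2179). The same holds for SHR minus SD (5187; 1 of 32, highest other 1333), WKY minus SD (2723; 1 of 32, highest other 1091) and the regions (3463; 1 of 100, highest other 2543). The splits exchange strain group labels within regions, or for the regions the region labels within strain groups, so they bear on grouping of arrays and say nothing of variation between rats. Chance cannot be excluded for the numbers of gene lists: 16 of 32 splits gave at least the 3 lists of SHR minus WKY (highest other 6) and 9 of 32 at least the 5 of SD-PCB minus SD (highest other 8). For SHR minus SD 6 of 32 gave at least the 3 lists (highest other 7), and for WKY minus SD 4 of 32 at least the 6 lists (highest other 6). It cannot be excluded for the size of the correlation between the models either (r = -0.25; 16 of 100 splits as large, highest other 0.380).

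The first pattern is the 4894 probe sets that differed between SD-PCB and SD, while the median signal of the SD-PCB arrays was lower. The signal distribution alone is argued against: after quantile normalization, which makes the distributions equal, 27.8% of the brightest 25% of probe sets passed (2161 of 7761, with 1118 higher and 1043 lower). With the median signal of the array as a covariate 0 of all tested passed (1639 at an unadjusted p under 0.05 in limma), and with the Gapdh ratio 154. Strain group explained 76.2% and 78.7% of the variance of these measures, so the covariate fits cannot separate them from exposure. Array processing that followed the strain groups stays open, since the added hybridisation controls, which hold no rat RNA, differed by a median log2 of -0.77 between SD-PCB and SD. All SD-PCB arrays share exposure and any processing step, so these cannot be told apart for this comparison. A response to the exposure stays open as well and was not tested.

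The second pattern is the low signal of dopamine neuron transcripts on the SD-PCB array of substantia nigra/VTA, where Slc6a3 (log2 9.90) lay outside the other arrays (nearest 12.53) and 10 detected markers had a median log2 difference of -1.80 from SD. Of these 10, 8 were lower and 2 higher (Nr4a2 0.46, Calb1 1.05), and the 6 above the signal filter had a median of -1.06. Th was also lower in SD-PCB than in SD in each other region, at dim signals (dorsal striatum 1.29 against 249, vermis 16.1 against 91.2). Slc6a3 was lower in each other region except the hippocampus (27.2 against 12.3). The low signal of these 2 genes was therefore not confined to this array. Medium spiny neuron markers differed by a median of 0.13 on the striatal SD-PCB arrays, which argues against lower sensitivity there for these markers. Some of them are bright (Drd1 5509 on average in the dorsal striatum), so dim transcripts are not covered. On these arrays 40.0% (dorsal) and 39.0% (ventral) of probe sets lay under 50, against 19.9% and 20.8% in SD. The marker test also does not cover the substantia nigra/VTA array itself, whose BioB control was the lowest of the SD-PCB arrays (log2 11.35). Neighbouring hypothalamic tissue in the sample may account for part of it: hypothalamic transcripts not looked at before had a median log2 difference of 1.70 over the 9 that reached a signal of 100 in SD or SD-PCB. Of all 13 on the array, dim ones included, 12 were higher and 1 lower (Nr5a1, 82.1 in SD and 27.3 in SD-PCB), with a median of 1.45. Among the 9 were Hcrt (113 in SD and 1900 in SD-PCB) and Nkx2-1 (351 and 2111). Pmch, seen before, was at 2447 and 13017 and Oxt at 156 and 1283. The SHR array held some such transcripts (Oxt 9747, Pmch 9765) and less of others (Hcrt 454, Nkx2-1 480), and its Th (3742) and Slc6a3 (8411) were not low, so it does not settle how much of the fall such tissue accounts for. An effect of exposure on dopamine neurons was not tested and stays open, with 1 array per strain group in this region.

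The third pattern is the rise of meningeal and vessel markers from WKY to SHR. The signal distribution of the arrays is argued against, because the 18 markers had a median log2 difference of 1.12 after quantile normalization and 1.28 as deposited. More meningeal and vessel tissue in the SHR samples, or less in the WKY samples, cannot be told apart from a strain difference in the transcripts themselves. In SHR minus WKY 11 of 12 region medians of the lists lay above 0.5 (0.45 to 1.93), and Hbb was higher too (1.71), which either would give. Against SD, meningeal region medians ran from -0.28 to 0.77 in SHR and from -1.84 to -0.67 in WKY, so these markers were low in WKY more than high in SHR. Vessel medians ran from 0.12 to 0.90 in SHR and from -0.66 to -0.11 in WKY. A strain difference in the transcripts themselves, in brain vessels of a hypertensive strain, was not tested and stays open.

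Arrays far from the others of their strain group came mostly from the vermis. Of 167 groups of 4 to 6 values tested, 24 held a value far from the rest by its gap to the nearest other, and chance flags about 1 in 20 groups. Of array measures, 12 of 32 did: the SD-PCB vermis array had a median signal of 126 (nearest other 94.8), 25.7% of probe sets under 50 (nearest 38.9%), and log2 hybridisation controls of 12.60 (BioB), 15.10 (BioDn) and 15.996 (CreX). The WKY vermis array had a median signal of 153 (nearest 122), 22.2% under 50 (nearest 30.8%), and controls of 12.15 (BioB), 12.28 (BioC), 15.13 (BioDn) and 16.17 (CreX), and the SHR vermis array 14.66 (BioDn). Th stood out on the SD array of the vermis (log2 6.53, nearest 4.10).

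Some differences rested unevenly on regions. Chi3l1 in SHR minus WKY was 3.0003 in substantia nigra/VTA (nearest other region 2.00), and Prune1 -3.27 in the hippocampus (nearest -2.62). Rasl12 in SD-PCB minus SD was -4.05 in the ventral striatum (nearest -2.20). In SHR minus SD, Pdlim7 was 6.08 in the vermis (nearest 1.30), Fam111a -1.16 in the vermis (nearest -3.12) and Pcdhb17 -5.34 in the hippocampus (nearest -2.20). Of the list medians, calcium handling in SHR minus WKY was -0.016 in the hippocampus (nearest -0.16). The ribosomal list in SD-PCB minus SD was 0.34 in the vermis (nearest -0.33), and in WKY minus SD oligodendrocyte markers were 0.32 (nearest -0.28) and astrocyte markers -0.025 (nearest -0.45) in the vermis. In the striatum term of SD-PCB minus SD, 1 probe set differed from the other regions, of Zbtb47.

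Control probe sets for non-rat sequences, which no comparison uses, differed too: 25 of 45 passed for SHR minus WKY, 39 for SD-PCB minus SD, 18 for SHR minus SD and 31 for WKY minus SD.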

How the results depend on the processing

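Alternatives added only after the data were seen were cyclic loess normalization, the Gapdh ratio or the median signal of each array as a covariate, leaving out the WKY prefrontal cortex and SD-PCB substantia nigra/VTA arrays, and quantile normalization with the upper 25%. With quantile normalization SHR minus WKY, SD-PCB minus SD, SHR minus SD and WKY minus SD had 4692, 3767, 5348 and 2212 probe sets past the threshold. Of these 4116, 2900, 4576 and 1715 were called as deposited. Without the pair of arrays the counts were 4150, 4330, 5217 and 2299. Fewer probe sets are tested in the upper 25% (3105, 2780, 3216 and 1782), in the upper 25% after quantile normalization (3236, 2161, 3061 and 1190) and with 1 probe set per gene (3139, 2493, 3312 and 1533), which lowers the counts by construction. The difference of the models had 3567, 3381 and 3620 under these. The upper 25% after quantile normalization changes the scaling as well, so its counts do not follow from the number tested alone. With no filter SD-PCB minus SD had 11079, WKY minus SD 4889 and the difference of the models 13230; array weights gave 7681 for SHR minus WKY and 4205 for WKY minus SD. With the Gapdh covariate SHR minus WKY had 3174, SD-PCB minus SD 154, SHR minus SD 2533 and the difference 2942. With the median signal as a covariate SHR minus WKY had 853, SD-PCB minus SD 0 (1639 at an unadjusted p under 0.05 in limma), WKY minus SD 74 and the difference 2. Strain group explained 78.7% of the variance of the Gapdh ratio and 76.2% of that of the median signal, and these covariates widened the standard error of SD-PCB minus SD 2.46 and 3.32 times. For the other changes the cause was not tested.

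Leaving out the arrays of each region in turn gave 3216 to 5701 probe sets for SHR minus WKY, 3608 to 5255 for SD-PCB minus SD, 3776 to 4942 for SHR minus SD, 1657 to 3100 for WKY minus SD and 4661 to 7048 for the difference of the models. The striatum terms had 0 to 1 for SHR minus WKY and 0 to 12 for SD-PCB minus SD; in these fits a lone striatal array is assumed to vary like the others. Lists shifted numbered 3 to 4, 5 to 7, 3 to 5 and 4 to 7 in the order above, and the correlation between the models ran from -0.304 to -0.151. Leaving out each strain group in turn gave 3529 to 3634 region probe sets in all, 713 to 877 in the dorsal striatum and 261 to 313 in the ventral striatum. It gave 677 to 780 in the prefrontal cortex, 343 to 484 in the hippocampus, 1067 to 1410 in substantia nigra/VTA and 2279 to 2516 in the vermis. With no filter these were 7372 in all, 1173 in the prefrontal cortex, 1854 in substantia nigra/VTA and 5483 in the vermis.

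The striatum term of SHR minus WKY, at 0, became 1 without the trend and 4 with array weights. That of SD-PCB minus SD, at 1, became 2 with quantile or cyclic loess normalization, no trend, array weights or 1 probe set per gene. It became 0 with a pseudocount of 16, the upper 25%, the median signal as a covariate, without the pair of arrays, or with quantile normalization and the upper 25% (813, 295, 451, 746 and 250 at an unadjusted p under 0.05 in limma). The correlation between the models, -0.253, was -0.117 with quantile normalization, -0.165 with cyclic loess, -0.472 with no filter and -0.575 with the median signal as a covariate, and it turned to 0.272 with the Gapdh covariate and 0.150 with SHR minus SD in place of SHR minus WKY.

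Gene lists shifted numbered 0 with an estimated correlation in all 4 comparisons (3, 4, 4 and 5 at an unadjusted p under 0.05) and 14, 14, 14 and 12 by fry. They numbered 5 for SHR minus WKY and 1 for SHR minus SD with cyclic loess, 2 for SD-PCB minus SD with no filter, and 1 for SHR minus SD and 3 for WKY minus SD with quantile normalization. Of the 20 list calls, the difference of the models included, 15 passed with quantile normalization, 18 with cyclic loess, 13 with no filter, 19 by fry and 19 without the pair of arrays, and 0 turned direction. The call lost by fry (adjusted p = 0.176) and without the pair (0.0587) was that of oligodendrocyte markers in WKY minus SD. Quantile normalization also shrank astrocyte medians that still passed, in SD-PCB minus SD from -0.46 to -0.29, in WKY minus SD from -0.46 to -0.18 and in the difference of the models from 0.65 to 0.33. Cyclic loess took the calcium median of SHR minus WKY from -0.17 to -0.083.

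Of 250 gene differences named in the text, 214 kept their direction and side of the threshold with quantile normalization, 33 fell short of it, 1 passed newly and 2 turned, both in SD-PCB minus SD: Snap25 to 0.31 (also 0.31 in the upper 25%) and C1qb, not past the threshold, to 0.0861. With the Gapdh covariate 144 held and 4 turned, in SD-PCB minus SD: Arc to 0.64, Vamp2 to -0.72, Hsd11b1 to 0.00627 and Calb1, not past the threshold, to -0.0979. Leaving out regions in turn, Calb1 ran from -0.0205, without substantia nigra/VTA, to 0.252. With the median signal 84 held and 15 turned: Tek to -0.0580, Rpl4 to 0.00432, Rpl19 to 0.23, Sv2b to 0.11 and Snap25 to 0.0513 in SD-PCB minus SD. Others were Hdac2 to -0.25, Hdac3 to -0.52, Sin3a to 0.0919, Cyp1b1 to 0.38, Gstp1 to -0.0658, Nfe2l2 to 0.49, Mbp to 0.0777, Prune1 to -0.44 and Ces1c to 0.49 in SD-PCB minus SD, and Rpl5 to 0.14 in WKY minus SD. The cause was not tested. Leaving out 1 region ended the call of 12 of 84 named gene differences in SHR minus WKY, 16 of 86 in SD-PCB minus SD, 1 of 28 in SHR minus SD and 2 of 31 in WKY minus SD, as given beside these genes. With 6 regions the exact sign-flip permutation gives a p under 0.05 only where all 6 have 1 sign, a rule by which many of these genes were chosen, so it says nothing on their stability. Signal near background limits dim probe sets, since no detection calls are given.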

Other observations

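The count of cerebellar transcripts on the prefrontal cortex arrays was taken only after the high Gabra6 signal there was seen. On the WKY array of the prefrontal cortex, Gabra6 reached 2297, against 28.8 to 97.0 on the prefrontal arrays of the other strain groups and 22310 on the WKY array of the vermis, and Pcp2 reached 668, against 29.4 to 76.2 and 12009. Of 50 vermis genes chosen without the WKY arrays, 30 were highest on the WKY prefrontal array, 11 on the SD array, 5 on the SD-PCB array and 4 on the SHR array. Their median signal there was 361, against 231 in SD, 180 in SD-PCB and 197 in SHR. The excess over the other prefrontal arrays had a median of 2.75% of the signal of these genes on the WKY vermis array.

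The dopamine receptor and signalling list stood above random lists of like signal within some regions, as values from 1 array against 1 array. For SHR minus WKY its median was 0.66 in the hippocampus and 0.72 in substantia nigra/VTA, and for SD-PCB minus SD 0.55 in the hippocampus, where medium spiny neuron markers had a median of 1.07. Choroid plexus and ependymal markers varied between samples: for SHR minus WKY their median was 1.38 in the ventral striatum and 1.38 in the vermis, and for SD-PCB minus SD it was -1.40 in the prefrontal cortex and -1.34 in substantia nigra/VTA but 1.53 in the vermis. Myelin markers had a median of 0.77 in the prefrontal cortex for SHR minus WKY. Oxidative phosphorylation genes had 0.37 to 0.40 in the ventral striatum, prefrontal cortex and substantia nigra/VTA of SHR minus WKY, and -0.64 in substantia nigra/VTA of SD-PCB minus SD.

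Arrays resembled both their region and their strain group. Over the tested probe sets the median correlation was 0.914 for pairs of the same region, 0.889 for pairs of the same strain group and 0.850 for pairs that shared neither. Of 24 arrays 15 correlated best with an array of their own strain group and 9 with an array of their own region.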
